A study of Mus musculus with 38 samples.

How the data were processed

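The series holds 38 RNA-seq libraries from female C57BL/6J mice aged 7 to 12 weeks that ate a high carbohydrate or a high protein diet for 5 days and were sampled at zeitgeber hour 8, per the labels. 8 libraries are of intestinal epithelial cells (IEC), 4 per diet, made from poly(A) RNA with a TruSeq kit. The other 30 are of sorted T cells made with SMART-seq2, a full-length protocol for small inputs. The sort took CD45-positive, EpCAM-negative cells and separated γδ from αβ T cells by their receptor, from the epithelial layer (IELgd and IELab) and from the lamina propria below it (LPgd and LPab). There are 4 libraries per diet of IELgd, IELab and LPab and 3 per diet of LPgd. The labels do not say that each library came from its own mouse, so p-values measure the spread between these libraries, which may in part be technical.

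The authors deposited 1 table per library with estimated counts, TPM and effective lengths for 126782 transcripts. Per the submitters' processing notes, kallisto 0.45.0 and sleuth were used with the mm10 and GRCm38 builds, and no role is given for each. The estimated counts deposited by the authors are not normalized, and kallisto shares reads between similar transcripts, so values of near-identical genes such as the Gsta and Defa families, and of overlapping antisense genes, are uncertain. TPM values in the deposited tables are scaled by the authors' tool to transcript length and library total.

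From these tables, estimated counts were summed to genes with the GENCODE annotation of GRCm38 and rounded to whole numbers. 1600 transcripts had no gene in that annotation and held 0.303 to 1.35% of the counts of a library. They were left out of the tests. Coordinates are those of GRCm38. Library totals ran from 284149 to 7308793 counts in epithelium and from 2666187 to 17699582 in the T cell libraries. Between any 2 replicates of a group the counts differed by more than sampling noise, so every library was counted once.

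Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 and their standard error is the fold change divided by the square root of F. The diet effect is high carbohydrate minus high protein. It was fitted within each population on that population's libraries. Differences between diet effects (interactions) and between populations were fitted on the 4 groups concerned, and population contrasts average both diets. CPM values use TMM-scaled totals of the libraries of a population. The fitted fold change of a gene near 0 counts in 1 group depends on edgeR's prior count, so CPM values are given for some such genes. For others, such as Jag2, the size of the fold change is uncertain. Gene lists were tested for a shared direction with fry from limma 3.58.1, on log2 CPM with a prior count of 2, and again with camera and an estimated correlation between genes. Of 50 lists of 645 genes, a list was tested where at least 3 members were measured. Single values per library were compared by exact 2-sided permutation tests over all splits, adjusted over the 25 tests of that family.

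The direction of each list that passed was also checked as the median over its members under TMM, DESeq2 size factors and TPM.

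The genes to name, the gene lists, the tests and most alternatives were fixed before the data were examined. Named genes are the 8 with the largest change in each direction among those past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups (overlap was not considered for interactions), the 4 with the smallest p in each direction, up to 4 members past the threshold of each list, and a fixed set given whatever its result. That set is Sis, Slc5a1, Slc2a2, Slc2a5, Khk, Slc15a1, Slc6a19, Anpep and Reg3g in epithelium and Il22, Il17a, Gzma, Gzmb, Jag2, Ahr and Areg in T cells, and 2 further members are not reported here. Unnamed gene models, pseudogenes and variable segments of antigen receptors were left out of the first parts of the rule, and the text names a share of the genes it gives.

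The tests across genes were checked on counts simulated from the libraries' own means and totals with 200 genes changed by 1.5, 2, 4 or 16-fold. edgeR, fry and camera were checked in all 12 comparisons. DESeq2, voom, limma on TPM, DESeq2 size factors and the replicate block were checked in the 5 diet comparisons alone, and the other alternatives and the exact permutation tests were not checked this way. The 16-fold size was added after sizes up to 4-fold gave few or no interaction calls. Recovery is given for edgeR. With 11427 genes in the epithelial diet step, 36% of the genes changed 2-fold and 94.2% of those changed 4-fold were recovered. At 4-fold, recovery was 37% in IELgd (12117 genes), 16% in LPgd (10497 genes), 26% in IELab (10014 genes) and 56.8% in LPab (12665 genes). At 16-fold it was 91.7%, 69.6%, 93% and 87.5% in the same order. For the interactions at 4-fold and 16-fold it was 7.4% and 57.5% for IELgd and IELab (11940 genes), 9.5% and 56% for LPgd and LPab (13467 genes) and 4% and 52.4% for IELgd and LPgd (13404 genes). For the populations at 4-fold it was 80.5% for IELgd and IELab (11835 genes), 58.5% for LPgd and LPab (13455 genes), 39% for IELgd and LPgd (13418 genes) and 64% for IELab and LPab (11960 genes). Genes simulated as unchanged made up 31 of 114 DESeq2 calls in IELgd, 40 of 112 in LPgd, 14 of 99 in IELab and 26 of 116 in LPab, against 4 of 69, 6 of 53, 2 of 69 and 7 of 83 edgeR calls. Lists of 20 raised genes had an unadjusted p of at most 0.00063 with fry and 0.00332 with camera. Of the lists of 20 unchanged genes, 1 had a fry p under 0.05, with 0.0381 for diet in IELab (10420 genes). Genes were simulated independently, so these checks cannot show how the list tests behave where genes are correlated.

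The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with quality weights, limma on log2(TPM + 1) for genes with a TPM of at least 1, no filter on low counts, a CPM of at least 5, an offset for transcript length, the replicate number as a block, all T cell libraries in 1 fit, a fold change of at least 2 and leaving out each library. After seeing the data, 4 more were added: the share of counts on ribosomal RNA models as a covariate, leaving out these 357 models and transcripts with a run of at least 24 G or C bases, and leaving out 2 or 3 epithelial libraries.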

Results

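Transcripts of intestinal epithelium and of 4 sorted intestinal T cell populations were counted in mice fed a high carbohydrate or a high protein diet for 5 days. The design asks which genes of each population differ between the diets, whether the diet effect differs between populations, and how γδ and αβ T cells of the epithelial layer and the lamina propria differ. Epithelial libraries held 284149 counts on genes (high carbohydrate replicate 1) or 4011572 to 7308793 (the other 7). IELgd libraries held 4567479 to 15118962, LPgd 3595880 to 7855667, IELab 2666187 to 4273341 and LPab 4140015 to 17699582.

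The first comparison asks how epithelial cells differ between the diets. In epithelial cells, 4 of the 9 measured fructose and gluconeogenesis genes rose and 1 fell on high carbohydrate, or 5 and 1 when adjusted over the list alone, and the list as a whole did not pass (fry adjusted p = 0.0621; 0.0105 without high carbohydrate replicate 2 and 0.0429 without high protein replicate 2). Slc2a5, the fructose transporter (chromosome 4, 150119283 to 150144169), averaged 604 ± 162 CPM (SD, n = 4) on high carbohydrate and 113 ± 36.8 CPM (n = 4) on high protein, a log2 fold change of 2.41 ± 0.26 (SE, adjusted p = 0.00204). Fbp1, a gluconeogenic phosphatase (chromosome 13, 62864753 to 62888282), averaged 219 ± 68.5 against 34.3 ± 9.34 CPM (log2 fold change 2.64 ± 0.28, adjusted p = 0.0017). Tkfc, which phosphorylates glyceraldehyde from fructose, rose by 1.78 ± 0.21 on the log2 scale. The member that fell was Pck1, a gluconeogenic enzyme, with 309 ± 138 CPM on high carbohydrate and 1095 ± 380 CPM on high protein (log2 fold change -1.80 ± 0.31, adjusted p = 0.031). G6pc, which releases free glucose, rose by 2.49 ± 0.46. The calls of Pck1 and G6pc ended when certain single libraries were left out (adjusted p without each in parentheses), which also leaves fewer samples. Pck1 did not pass without any 1 of high carbohydrate replicates 1, 2 and 3 (0.136, 0.063 and 0.113) and high protein replicate 4 (0.0724). G6pc did not pass without any 1 of high carbohydrate replicates 1, 3 and 4 (0.145, 0.113 and 0.172) and high protein replicates 1, 3 and 4 (0.0833, 0.0884 and 0.0687).

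**Figure D1:**
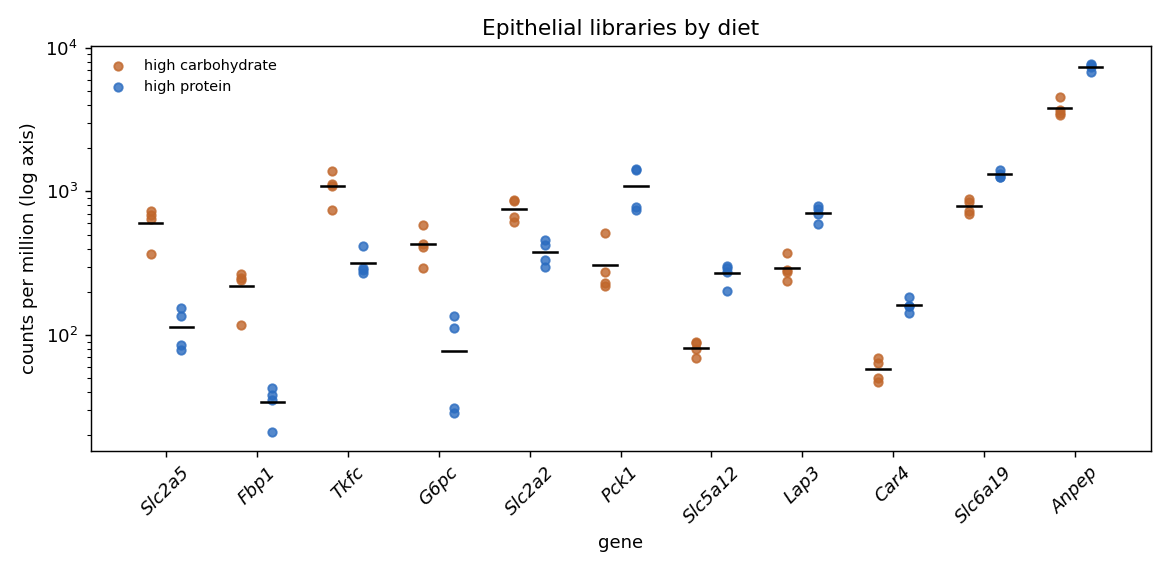
CPM values (log axis) of 11 genes in the 8 epithelial libraries, with 1 point per library, high carbohydrate in orange, high protein in blue and a bar at the mean of 4 libraries. Slc2a5 averaged 604 CPM on high carbohydrate and 113 CPM on high protein, and Slc5a12 averaged 81.4 and 268 CPM.

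Slc2a2, the basolateral glucose transporter, rose by 0.99 ± 0.18 and Gpi1, a glycolytic isomerase, by 0.99 ± 0.17. Slc2a2 did not pass without any 1 of high carbohydrate replicates 1, 3 and 4 (adjusted p = 0.145, 0.124 and 0.0978) and high protein replicates 1, 3 and 4 (0.0571, 0.113 and 0.126). Gpi1 did not pass without any 1 of high carbohydrate replicates 1, 3 and 4 (0.0997, 0.0865 and 0.0978) and high protein replicates 1, 3 and 4 (0.0969, 0.113 and 0.0759). Of 11 carbohydrate digestion and transport genes 2 rose, 8 when adjusted over the list alone, and the list had an adjusted p of 0.0778 (0.0105 without high carbohydrate replicate 2). The fructokinase Khk (log2 fold change 0.97 ± 0.20, adjusted p = 0.0723; 0.0197 and 0.021 without replicate 2 of high carbohydrate and of high protein), the disaccharidase Sis (1.16 ± 0.30, adjusted p = 0.169) and the glucose cotransporter Slc5a1 (0.55 ± 0.21, adjusted p = 0.515) did not pass. Of 16 glycolysis genes 1 rose (5 adjusted over the list alone; list adjusted p = 0.0719, and 0.0105 without high carbohydrate replicate 2). Txnip and Arrdc4, glucose-responsive arrestin genes, rose by 1.24 ± 0.16 and 1.29 ± 0.17. Their list of carbohydrate-response and lipogenic genes (14 measured, 2 past the threshold, 6 adjusted over the list alone) rose with a fry adjusted p of 0.00795, and had an adjusted p = 0.0571 with an estimated correlation.

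Slc5a12, a monocarboxylate cotransporter (chromosome 2, 110597298 to 110647779), averaged 81.4 ± 9.0 CPM on high carbohydrate and 268 ± 45.7 CPM on high protein (log2 fold change -1.74 ± 0.16, adjusted p = 0.00118). The aminopeptidase Lap3 (log2 fold change -1.28 ± 0.17), the carbonic anhydrase Car4 (-1.45 ± 0.15) and the nuclease Dnase1 (-1.56 ± 0.20) also fell on high carbohydrate. Peptide digestion genes as a list (16 measured, 1 lower, 5 lower when adjusted over the list alone) fell with a fry adjusted p of 0.00944, and had an adjusted p = 0.132 with an estimated correlation and an adjusted p = 0.0508 without high carbohydrate replicate 1. Amino acid transporters (18 measured, 0 past the threshold; adjusted over the list alone 5 lower and 2 higher) fell with a fry adjusted p of 0.00794, and also had an adjusted p = 0.132 with an estimated correlation. The amino acid transporter Slc6a19 (-0.73 ± 0.14, adjusted p = 0.052), the aminopeptidase Anpep (-0.95 ± 0.19, adjusted p = 0.052) and the peptide transporter Slc15a1 (-0.67 ± 0.20, adjusted p = 0.255) did not pass.

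The nucleic acid sensor Zbp1 (log2 fold change -1.79 ± 0.29), the fucosyltransferase Fut2 (-2.93 ± 0.50) and the oxidase maturation factor Duoxa2 (-2.77 ± 0.51) fell. Zbp1 did not pass without any 1 of high carbohydrate replicates 2, 3 and 4 (adjusted p = 0.0588, 0.0966 and 0.147) and high protein replicate 1 (0.0606). Fut2 did not pass without any 1 of high carbohydrate replicates 1, 3 and 4 (0.0819, 0.113 and 0.197) and high protein replicates 1, 3 and 4 (0.0541, 0.105 and 0.0921). Duoxa2 did not pass without any 1 of high carbohydrate replicates 1, 3 and 4 (0.109, 0.136 and 0.236) and high protein replicates 1, 3 and 4 (0.083, 0.169 and 0.126). Interferon response genes (17 measured, 1 lower, 9 adjusted over the list alone) fell with a fry adjusted p of 0.0477, and had an adjusted p = 0.132 with an estimated correlation. That call ended without any 1 of high carbohydrate replicates 1, 3 and 4 (adjusted p = 0.0592, 0.0714 and 0.171) and high protein replicates 1, 2, 3 and 4 (0.107, 0.062, 0.158 and 0.124). Of 12 antimicrobial genes 2 were lower (7 adjusted over the list alone; list adjusted p = 0.0692, and 0.022 without high carbohydrate replicate 3), and Reg3g, an antimicrobial lectin, had a log2 fold change of -1.76 ± 0.52 (adjusted p = 0.261). Among other genes, the carotenoid oxygenase Bco1 rose by 2.72 ± 0.35, the epoxide hydrolase Ephx1 by 2.88 ± 0.41, the glutathione transferases Gsta3 and Gsta4 by 2.01 ± 0.32 and 1.48 ± 0.23, the growth factor Nrg4 by 1.93 ± 0.25 and Pbx4 by 5.25 ± 0.50. Gsta3 did not pass without any 1 of high carbohydrate replicates 1, 3 and 4 (0.053, 0.0865 and 0.0978) and high protein replicates 3 and 4 (0.0625 and 0.0685). Gsta4 did not pass without any 1 of high carbohydrate replicates 1, 3 and 4 (0.0717, 0.0681 and 0.0715) and high protein replicates 1 and 3 (0.0571 and 0.0625). Lists of stem cell (11 measured), proliferation (21), goblet (9), Paneth (9), enteroendocrine (14) and tuft (9) genes held 0 genes past the threshold each, with list adjusted p from 0.632 to 0.899, and the proliferation list had 0.0452 without high carbohydrate replicate 2. Markers of T cells (12 measured) had a median log2 fold change of -0.69 (list adjusted p = 0.173).

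In all, 54 of 11734 genes passed in epithelium, 35 higher and 19 lower on high carbohydrate, and 898 had an unadjusted p under 0.05. Without overlap between the diets were 633 genes (5.39%), where chance gives 2.86% for 4 against 4. That share was 5.02% in IELgd, 5.59% in LPab and 1.58% in IELab, where edgeR called 0 genes for diet, so it is not particular to epithelium. Leaving out high carbohydrate replicates 1, 2, 3 and 4 in turn gave 24, 73, 22 and 17 genes, and leaving out high protein replicates 1, 2, 3 and 4 gave 26, 103, 22 and 32. No gene passed (0) with limma on log2(TPM + 1), while DESeq2 called 149, voom 188, edgeR without a filter on low counts 290 and edgeR with the length offset 34. Without the 3 libraries highest in Gm19220 (high carbohydrate replicates 1 and 2 and high protein replicate 2) 218 passed. The 4 list calls in epithelium (carbohydrate-response, peptide digestion, amino acid transport and interferon) ended without high carbohydrate replicate 1 and high protein replicate 2 together, with adjusted p from 0.0915 to 0.107. Carbohydrate-response and interferon genes also had an adjusted p of 0.0758 each without the 3 libraries highest in Gm19220.

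In T cells, edgeR called 0 genes for diet in 3 of the 4 populations, where DESeq2 called 224 (IELgd), 2 (IELab) and 240 (LPab). IELgd libraries had Gzma at 33824 ± 11453 CPM on high carbohydrate and 40735 ± 16090 CPM on high protein (n = 4 each, log2 fold change -0.27 ± 0.37, adjusted p = 0.817), and the cytotoxic gene Gzmb had a log2 fold change of 0.05 ± 0.29 (adjusted p = 0.967). Ahr, a receptor for dietary and microbial ligands, had -0.59 ± 0.31 (adjusted p = 0.542) and Jag2, a Notch ligand, -0.60 ± 0.93 (adjusted p = 0.84). In IELab, Gzma had 0.21 ± 0.61, Gzmb -0.29 ± 0.38 and Ahr -0.07 ± 0.46 (adjusted p = 1 each). In LPab, the cytokine Il17a averaged 95.1 ± 49.5 and 53.8 ± 18.9 CPM (log2 fold change 0.82 ± 0.40, adjusted p = 0.495) and Il22, which acts on epithelium, 99.0 ± 32.2 and 130 ± 42.6 CPM (-0.40 ± 0.30, adjusted p = 0.661). Areg, a growth factor, had -0.88 ± 0.44 (adjusted p = 0.499), Gzma -0.56 ± 0.33 (0.567), Ahr -0.37 ± 0.28 (0.666) and Gzmb -0.26 ± 0.27 (0.762) there. Il22, Il17a and Areg were below the count filter in IELgd and IELab, and Jag2 in IELab, LPab and LPgd.

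Of 12510 genes in IELgd, edgeR called 0, with 1279 at an unadjusted p under 0.05. Other tools called 224 (DESeq2), 0 (voom) and 2 (limma on TPM). With edgeR 407 passed without a filter on low counts, 44 without high protein replicate 1 and 1 without high protein replicate 4. Of 10420 genes in IELab, edgeR called 0 (261 unadjusted), DESeq2 2, voom 0, limma on TPM 1 and edgeR without a filter on low counts 122. Of 13171 genes in LPab, edgeR called 0 (1419 unadjusted), DESeq2 240, voom 17 and limma on TPM 2, and edgeR called 165 without a filter on low counts and 139 without high protein replicate 1.

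LPgd libraries had 18 of 11035 genes past the threshold, 16 higher and 2 lower on high carbohydrate, and 2131 at an unadjusted p under 0.05. Other tools called 961 (DESeq2), 39 (voom) and 52 (limma on TPM). With edgeR 861 passed without a filter on low counts, 33 at a CPM of at least 5, 65 with the length offset, 271 with all T cell libraries in 1 fit and 4 without ribosomal RNA and G or C run models. Pls1, an actin-bundling protein (chromosome 9, 95752642 to 95845311), averaged 60.4 ± 25.5 CPM on high carbohydrate and 0.578 ± 0.376 CPM on high protein (n = 3 each, log2 fold change 6.67 ± 0.71, adjusted p = 0.00828). The light chain gene Iglc3 rose by 4.46 ± 0.55, the transcription factor subunit Taf2 by 4.34 ± 0.60, the Wnt receptor Fzd5 by 3.25 ± 0.47 and the activation-induced receptor Nr4a1 by 2.48 ± 0.38, which averaged 1815 ± 502 and 326 ± 110 CPM. Also called were the ribosomal RNA models Gm42418 and Gm26917, higher by 3.85 and 4.73, and Gm19220, lower with -5.71. So were the pseudogenes Gm28661, Gm10359 and Gm12671, higher by 12.9, 11.8 and 11.8. The variable segment Igkv8-27 was higher by 8.04 and the miRNA model Gm26377 lower with -9.95. These models, pseudogenes and this segment were named after their values were seen. The calls of the other named genes ended when certain single libraries were left out (adjusted p without each in parentheses), which also leaves fewer samples. Pls1 did not pass without high carbohydrate replicate 1 (0.0804). Iglc3 did not pass without any 1 of high carbohydrate replicates 1 and 2 (0.104 and 0.0507) and high protein replicates 1, 2 and 3 (0.0605, 0.129 and 0.0738). Taf2 did not pass without any 1 of high carbohydrate replicates 1 and 3 (0.131 and 0.164) and high protein replicates 1, 2 and 3 (0.0643, 0.129 and 0.115). Fzd5 did not pass without any 1 of high carbohydrate replicates 1, 2 and 3 (0.105, 0.113 and 0.164) and high protein replicates 1, 2 and 3 (0.0764, 0.129 and 0.0929). Nr4a1 did not pass without any 1 of high carbohydrate replicates 1, 2 and 3 (0.104, 0.113 and 0.164) and high protein replicates 1, 2 and 3 (0.0704, 0.129 and 0.152). Taf2 (adjusted p = 0.0722) and Fzd5 (0.0561) did not pass with limma on log2(TPM + 1) either. Gzma had -1.98 ± 0.49 (adjusted p = 0.0992), Gzmb -0.91 ± 0.38 (0.23), Ahr 0.45 ± 0.37 (0.537), Il22 -0.44 ± 0.49 (0.667), Il17a -0.49 ± 0.86 (0.792) and Areg 0.15 ± 0.96 (0.955). Markers of T cells, which include Gzma and Gzmb, held 2.00 ± 0.564% of counts on high carbohydrate and 5.72 ± 2.52% on high protein. Markers of B and plasma cells held 2.59 ± 1.01% of counts on high carbohydrate and 1.62 ± 0.377% on high protein. Pancreatic exocrine markers held 1.18 ± 1.59% (0.138 to 3.02%) and 0.0945 ± 0.0775% (0.00813 to 0.158%), and myeloid markers 0.0244 ± 0.0052% and 0.035 ± 0.00811%. No list passed, though clock genes did without high carbohydrate replicate 2 (adjusted p = 0.0134), and 28.6% of genes did not overlap between diets, where chance gives 10% for 3 against 3. Leaving out LPgd high carbohydrate replicates 1, 2 and 3 left 4, 10 and 7 genes, and high protein replicates 1, 2 and 3 left 7, 4 and 10; 0 passed with the ribosomal RNA share as a covariate.

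The share of counts on ribosomal RNA models did not overlap between the diets in LPgd, LPab and IELgd, though no test passed after adjustment. It was 11.8 ± 8.72% on high carbohydrate and 1.26 ± 0.325% on high protein in LPgd (exact permutation p = 0.1, the smallest that 3 against 3 allows). In LPab it was 1.58 ± 0.258% and 8.09 ± 4.11%, and in IELgd 1.46 ± 0.632% and 6.01 ± 4.14% (exact permutation p = 0.0286 each, the smallest for 4 against 4, adjusted p = 0.238 over 25 tests). In IELab it was 5.20 ± 3.66% and 10.8 ± 5.53% (exact permutation p = 0.143). Other measures did not overlap between the diets either. In LPgd the share on retained introns was 4.55 ± 0.979% and 3.30 ± 0.202%, and that on Gm19220 0.0673 ± 0.00952% and 3.41 ± 2.07% (exact permutation p = 0.1 each, adjusted p = 0.417). In IELgd the mitochondrial share was 4.78 ± 0.457% and 3.11 ± 0.962% (exact permutation p = 0.0286, adjusted p = 0.238). Further measures without overlap were not tested singly. In LPgd they were the shares on T cell markers (1.38 to 2.48% and 2.82 to 7.38%) and on myeloid markers (0.01892 to 0.02925% and 0.02926 to 0.04427%) and the number of genes with a count of at least 5 (12904 to 13236 and 11033 to 11763). In IELgd they were the shares on transcripts outside the annotation (1.22 to 1.35% and 0.802 to 1.17%) and on erythroid markers (0.013 to 0.0324% and 0.0366 to 0.063%). In LPab the erythroid share was 0.00647 to 0.0126% and 0.0142 to 0.0269%. The erythroid list (5 measured, 0 past the threshold in each) had 2 genes lower in IELgd and 4 lower in LPab adjusted over the list alone, with fry adjusted p of 0.24 and 0.093, and in LPab passed without high protein replicate 3 (0.0122).

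**Figure D2:**
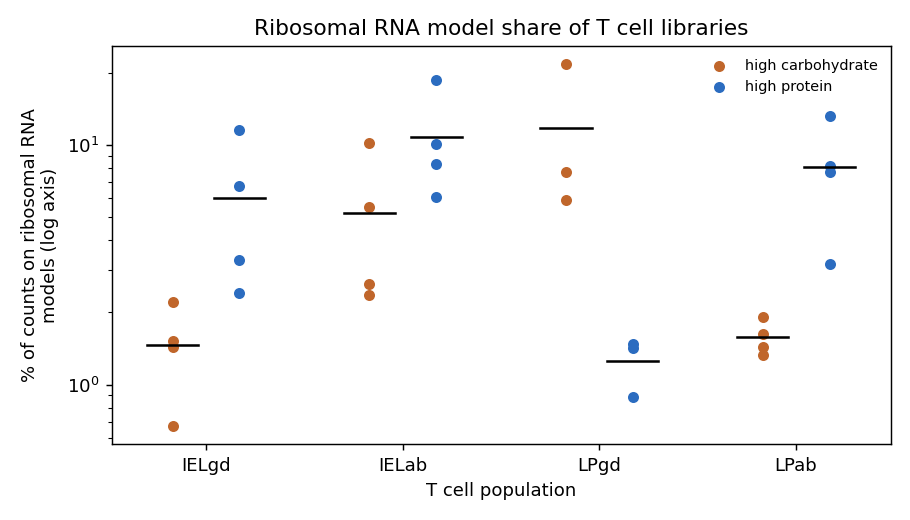
Percent of counts on ribosomal RNA models (log axis) in the 30 T cell libraries by population, with 1 point per library, high carbohydrate in orange, high protein in blue and a bar at the mean. LPgd averaged 11.8% on high carbohydrate and 1.26% on high protein, and LPab 1.58% and 8.09%.

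The diet effect differed between LPgd and LPab in 776 of 14006 genes, 654 with a larger log2 fold change in LPgd and 122 with a smaller one. The receptor Notch1 (chromosome 2, 26457903 to 26516663) averaged 231 ± 28.3 and 43.7 ± 23.2 CPM on high carbohydrate and high protein in LPgd and 76.1 ± 11.5 and 164 ± 65.6 CPM in LPab, a log2 difference of 3.44 ± 0.52 (adjusted p = 0.00478). Notch2 differed by 3.80 ± 0.69, Zfp683, a regulator of tissue-resident T cells, by 5.93 ± 0.98, Prdm1 by 3.40 ± 0.71, the clock gene Per1 by 3.16 ± 0.66 and the amino acid transporter Slc7a5 by 3.04 ± 0.75. Rsl24d1 and Mthfd2 differed by -2.31 ± 0.45 and -1.49 ± 0.39. Slc7a5 did not pass without any 1 of LPgd high carbohydrate replicate 1 (adjusted p = 0.0588), LPgd high protein replicates 2 and 3 (0.0512 and 0.0639), LPab high carbohydrate replicates 2, 3 and 4 (0.0598, 0.0568 and 0.0612) and LPab high protein replicate 3 (0.065). Mthfd2 did not pass without any 1 of LPgd high carbohydrate replicates 1 and 3 (0.109 and 0.0789), LPgd high protein replicates 1, 2 and 3 (0.0601, 0.0537 and 0.0718), LPab high carbohydrate replicates 1, 2 and 4 (0.0807, 0.0777 and 0.0724) and LPab high protein replicates 2, 3 and 4 (0.0538, 0.0755 and 0.0727). Per1 (adjusted p = 0.067) and Slc7a5 (0.0773) did not pass with limma on log2(TPM + 1). Lists with a higher log2 fold change (high carbohydrate minus high protein) in LPgd than in LPab by fry were amino acid transport (15 measured, 1 higher, 2 adjusted over the list alone, adjusted p = 0.0364), tissue residency (14 measured, 4 higher, 4 adjusted over the list alone, 0.0364) and Notch (9 measured, 2 higher, 4 adjusted over the list alone, 0.0493). The γδ receptor list (4 measured, 0 past the threshold, 0 adjusted over the list alone, adjusted p = 0.0266) and the αβ receptor list (3 measured, 0 past the threshold, 3 lower adjusted over the list alone, 0.022) had a lower fold change of this kind in LPgd than in LPab. All 5 lists had an adjusted p = 0.675 with an estimated correlation. Each of these list calls ended when certain single libraries were left out (adjusted p without each in parentheses), which also leaves fewer samples. Amino acid transport did not pass without any 1 of LPgd high carbohydrate replicates 1 and 2 (0.0621 and 0.0586), LPgd high protein replicate 2 (0.0516), LPab high carbohydrate replicates 2, 3 and 4 (0.0671, 0.0529 and 0.0524) and LPab high protein replicate 3 (0.0754). Tissue residency did not pass without any 1 of LPgd high carbohydrate replicates 1 and 2 (0.0586 and 0.0586), LPgd high protein replicate 2 (0.0516), LPab high carbohydrate replicates 2, 3 and 4 (0.0671, 0.0588 and 0.0524) and LPab high protein replicates 3 and 4 (0.0808 and 0.076). The Notch list did not pass without any 1 of LPgd high carbohydrate replicates 1, 2 and 3 (0.0868, 0.0586 and 0.112), LPgd high protein replicate 2 (0.078), LPab high carbohydrate replicates 2, 3 and 4 (0.0787, 0.0776 and 0.088) and LPab high protein replicates 2, 3 and 4 (0.059, 0.1 and 0.103). The γδ receptor list did not pass without any 1 of LPgd high carbohydrate replicates 1 and 2 (0.0983 and 0.0524), LPgd high protein replicate 2 (0.108), LPab high carbohydrate replicates 1, 2 and 4 (0.12, 0.0618 and 0.0521) and LPab high protein replicate 1 (0.0604). The αβ receptor list did not pass without LPgd high protein replicate 2 (0.0516). Of the genes given whatever their result, none passed, with log2 differences of -1.48 ± 0.60 for Gzma (adjusted p = 0.137), -1.42 ± 0.75 for Il17a (0.247), 0.74 ± 0.43 for Ahr (0.297), -0.73 ± 0.45 for Gzmb (0.321), 0.94 ± 0.87 for Areg (0.524) and -0.13 ± 0.58 for Il22 (0.918). Jag2 was below the count filter. With limma on log2(TPM + 1) the split was 539 to 228, DESeq2 called 1762 genes, 1165 passed without a filter on low counts and 0 with the ribosomal RNA share as a covariate. With that covariate the amino acid transport, tissue residency, Notch and αβ receptor lists had the opposite direction and did not pass. Without a single library the count ran from 358 to 1381, with moves of over 1.5 times without LPgd high carbohydrate replicate 1 (455), LPab high carbohydrate replicates 2, 3 and 4 (398, 449 and 363) and LPab high protein replicates 1, 3 and 4 (1381, 358 and 400).

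Between IELgd and LPgd the diet effect differed in 648 of 13844 genes, 47 with a larger log2 fold change in IELgd and 601 with a smaller one. Pls1 differed by -8.21 ± 0.76 (adjusted p = 0.000102), Notch1 by -4.15 ± 0.62, Per1 by -3.51 ± 0.67 and Slc7a5 by -3.37 ± 0.79. The receptor Klre1 differed by 3.33 ± 0.82, the respiratory chain gene Ndufb3 by 2.68 ± 0.60 and Sat1 by 2.09 ± 0.48. Slc7a5 did not pass without any 1 of IELgd high carbohydrate replicates 2 and 3 (adjusted p = 0.0516 and 0.0519), IELgd high protein replicate 3 (0.055), LPgd high carbohydrate replicate 1 (0.0758) and LPgd high protein replicates 2 and 3 (0.0713 and 0.0571). Klre1 did not pass without any 1 of IELgd high carbohydrate replicates 3 and 4 (0.0659 and 0.06), IELgd high protein replicate 4 (0.0553), LPgd high carbohydrate replicates 1, 2 and 3 (0.0505, 0.0543 and 0.0655) and LPgd high protein replicate 2 (0.0853). Ndufb3 did not pass without any 1 of LPgd high carbohydrate replicate 1 (0.0505) and LPgd high protein replicate 2 (0.0624). Sat1 did not pass without any 1 of LPgd high carbohydrate replicates 2 and 3 (0.0549 and 0.0563) and LPgd high protein replicate 2 (0.0658). Slc7a5 had an adjusted p of 0.056 with limma on log2(TPM + 1). Amino acid transport (18 measured, 2 lower, 4 adjusted over the list alone, fry adjusted p = 0.0263) and clock genes (14 measured, 2 lower, 5 adjusted over the list alone, 0.038) had a lower log2 fold change for diet in IELgd than in LPgd. Each had an adjusted p = 0.606 with an estimated correlation. Both list calls ended with DESeq2 size factors (adjusted p = 0.0527 each). The transport list did not pass without any 1 of IELgd high carbohydrate replicates 2 and 4 (0.107 and 0.0624), IELgd high protein replicate 3 (0.0662), LPgd high carbohydrate replicate 1 (0.0814) and LPgd high protein replicates 2 and 3 (0.101 and 0.0599). The clock list did not pass without any 1 of IELgd high carbohydrate replicates 1, 2, 3 and 4 (0.0972, 0.107, 0.0671 and 0.0624), IELgd high protein replicates 2 and 3 (0.0601 and 0.0662), LPgd high carbohydrate replicates 1 and 3 (0.104 and 0.106) and LPgd high protein replicates 2 and 3 (0.101 and 0.101). Gzma (log2 difference 1.72 ± 0.65, adjusted p = 0.132), Ahr (-1.04 ± 0.47, 0.205) and Gzmb (0.98 ± 0.47, 0.235) did not pass. Nor did genes near 0 counts in at least 1 group, which were Jag2 (-6.83 ± 2.67, 0.151), Il22 (3.71 ± 1.72, 0.221), Il17a (-1.91 ± 1.15, 0.352) and Areg (-2.16 ± 1.76, 0.502). With limma on log2(TPM + 1) the split was 133 to 338, DESeq2 called 1562 genes, 1274 passed without a filter on low counts and 3 with the ribosomal RNA share as a covariate. That share separated the diets in opposite directions in IELgd and LPgd. An effect of diet therefore cannot be told apart here from one that goes with the share. Counts moved by over 1.5 times without IELgd high carbohydrate replicates 2, 3 and 4 (371, 376 and 362), IELgd high protein replicates 1, 3 and 4 (982, 386 and 368), LPgd high carbohydrate replicate 1 (261) and LPgd high protein replicate 2 (217). Between IELgd and IELab, edgeR called 0 of 12241 genes, with 326 at an unadjusted p under 0.05, DESeq2 2, voom 0, limma on TPM 0 and edgeR without a filter on low counts 97. The log2 differences were 0.30 ± 0.44 for Gzmb, -0.54 ± 0.74 for Gzma, -0.55 ± 0.55 for Ahr and 0.061 ± 1.61 for Jag2 (adjusted p = 1 each), and Il22, Il17a and Areg were below the count filter.

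In the epithelial layer, γδ cells were higher in Trdc and Tcrg-C1 and lower in Cd4, Cd8b1 and lists of regulatory and naive T cell genes. Trdc, the δ receptor constant gene (chromosome 14, 54142851 to 54148868), averaged 1345 ± 215 and 2012 ± 430 CPM on high carbohydrate and high protein in IELgd. In IELab it averaged 6.86 ± 3.50 and 5.91 ± 2.54 CPM (log2 fold change 7.87 ± 0.36, adjusted p = 6.13e-11, n = 8 each). Tcrg-C1 was higher by 3.75 ± 0.30. The coreceptor genes Cd8b1 (log2 fold change -4.30 ± 0.31) and Cd4 (-7.06 ± 0.55) and the receptor inhibitor Cd5 (-5.06 ± 0.42) were lower in IELgd. Foxp3, the regulatory T cell factor, averaged 15.5 ± 16.6 and 20.4 ± 6.29 CPM in IELab and 0.0237 ± 0.0474 and 0.063 ± 0.126 CPM in IELgd (adjusted p = 5.34e-07). Of 8 regulatory T cell genes 4 were lower and 1 higher (5 and 1 adjusted over the list alone, fry adjusted p = 3.46e-06). Of 9 naive and circulating genes, such as Lef1 and Klf2, 8 were lower (also 8 adjusted over the list alone, fry adjusted p = 6.86e-06). Both lists had an adjusted p = 0.026 with an estimated correlation. Of 17 cytotoxic and NK receptor genes 4 were higher (5 adjusted over the list alone), among them Klrd1 by 2.31 ± 0.34 and Gzmb by 0.90 ± 0.22 (fry adjusted p = 0.00277, and adjusted p = 0.26 with an estimated correlation). Trac had a log2 fold change of -0.83 ± 0.24. It did not pass without any 1 of IELgd high carbohydrate replicates 1, 2, 3 and 4 (adjusted p = 0.0514, 0.0506, 0.0713 and 0.0639), IELgd high protein replicates 1 and 3 (0.0656 and 0.0824), IELab high carbohydrate replicates 1, 3 and 4 (0.0518, 0.0517 and 0.0616) and IELab high protein replicates 2 and 3 (0.0821 and 0.0562). It had an adjusted p of 0.293 with limma on log2(TPM + 1). Gzma had a log2 fold change of 1.06 ± 0.38 (adjusted p = 0.069), and passed with limma on log2(TPM + 1) (0.0188) and without any 1 of IELgd high protein replicate 4 (0.0488), IELab high carbohydrate replicate 1 (0.00781) and IELab high protein replicate 3 (0.048). Ahr (-0.43 ± 0.28, adjusted p = 0.313) and Jag2 (-0.72 ± 0.77, adjusted p = 0.574) did not pass, and Il22, Il17a and Areg were below the count filter. In all 1448 of 12241 genes passed, 621 higher and 827 lower in IELgd, and 503 passed with the ribosomal RNA share as a covariate. DESeq2 called 2259, voom 2351 and edgeR without a filter on low counts 2327. With limma on log2(TPM + 1) the split was 1502 to 364, and the median log2 fold change of that fit differed from that of edgeR by 0.32. Single libraries moved the count to 895 (without IELgd high carbohydrate replicate 3), 840 and 2272 (IELgd high protein replicates 1 and 4), 2325 and 910 (IELab high carbohydrate replicates 1 and 4) and 868 (IELab high protein replicate 2).

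**Figure D3:**
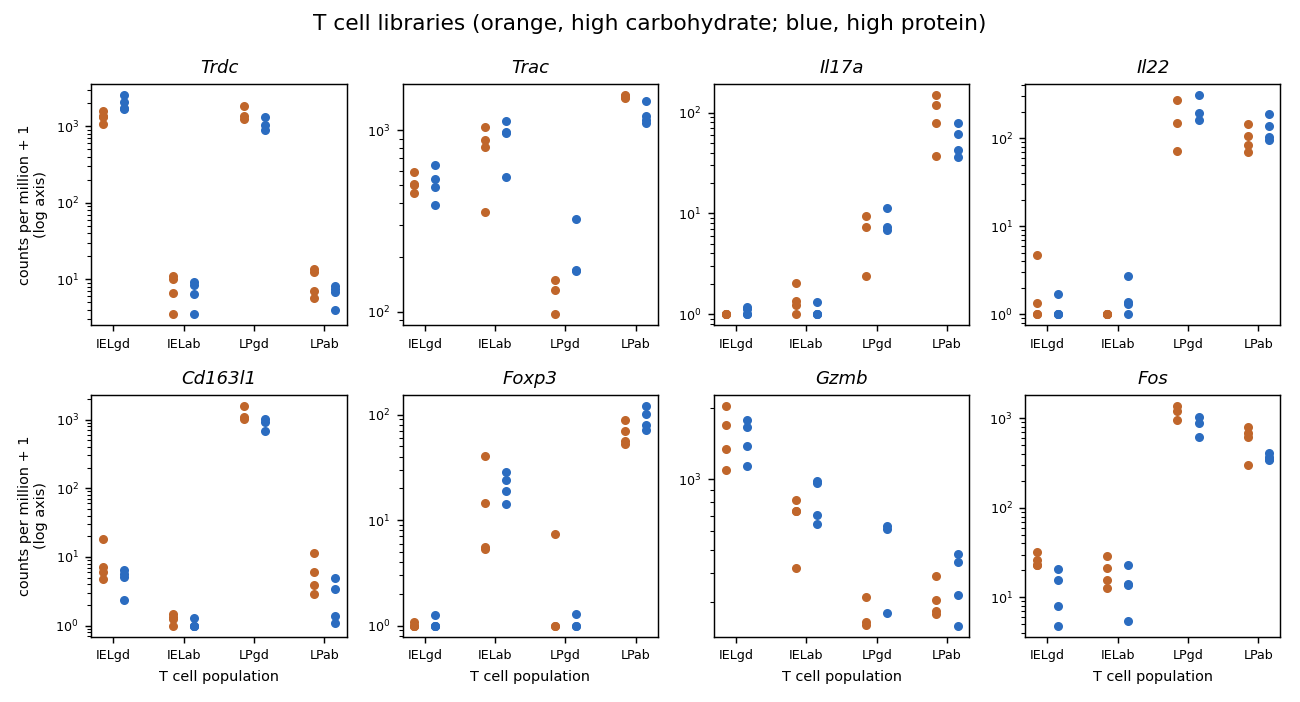
CPM values plus 1 (log axis) of 8 genes in the 30 T cell libraries, with 1 point per library, high carbohydrate in orange and high protein in blue. Trdc averaged 1345 CPM in IELgd and 6.86 CPM in IELab on high carbohydrate, and Fos averaged 1180 CPM in LPgd and 25.0 CPM in IELgd.

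In the lamina propria, γδ cells were higher in Cd163l1 and Blk and lower in Il17a. The scavenger receptor Cd163l1 (chromosome 7, 140218267 to 140231145) averaged 1220 ± 296 and 872 ± 167 CPM on high carbohydrate and high protein in LPgd (n = 3 each) and 5.10 ± 3.84 and 1.71 ± 1.83 CPM in LPab (n = 4 each), a log2 fold change of 8.51 ± 0.61 (adjusted p = 2.28e-07). The kinase Blk was higher by 5.11 ± 0.37, while Il17a was lower (log2 fold change -3.45 ± 0.42). Of 14 type 17 genes 7 were higher and 3 lower (8 and 3 adjusted over the list alone, fry adjusted p = 0.000261, and adjusted p = 0.202 with an estimated correlation). The growth factor Hbegf was higher by 4.08 ± 0.38 and Gzma by 1.94 ± 0.30. Ifng (log2 fold change -4.19 ± 0.40), Areg (-2.48 ± 0.47), Cd40lg (-4.27 ± 0.34) and Cd4 (-6.84 ± 0.41) were lower. Il22 did not pass (0.79 ± 0.29, adjusted p = 0.0981; 0.0369 without LPgd high carbohydrate replicate 2). Neither did Ahr (0.70 ± 0.21, adjusted p = 0.0524; 0.0279 without LPab high carbohydrate replicate 2 and 0.0299 with limma on log2(TPM + 1)) nor Gzmb (0.17 ± 0.22, adjusted p = 0.723), and Jag2 was below the count filter. Of 21 ribosomal protein genes 15 were lower (20 adjusted over the list alone, fry adjusted p = 0.000965, and adjusted p = 0.202 with an estimated correlation). Markers of other cells differed too. As lists, B and plasma cell markers were higher in LPgd (1 of 9, 3 adjusted over the list alone, fry adjusted p = 0.00811, and adjusted p = 0.202 with an estimated correlation). So were myeloid markers (1 of 10, 1 adjusted over the list alone, fry adjusted p = 0.00542, and adjusted p = 0.14 with an estimated correlation). Erythroid markers (5 measured, 0 past the threshold, 0 adjusted over the list alone, fry adjusted p = 0.0461, and adjusted p = 0.387 with an estimated correlation) were lower as a list. That call ended with DESeq2 size factors (adjusted p = 0.0532) and without ribosomal RNA and G or C run models (0.0504). It also ended without any 1 of LPgd high carbohydrate replicates 2 and 3 (0.105 and 0.0828), LPgd high protein replicate 3 (0.11), LPab high carbohydrate replicates 1, 2, 3 and 4 (0.0698, 0.0661, 0.0734 and 0.0777) and LPab high protein replicates 1, 2 and 4 (0.0788, 0.0777 and 0.0688). Epithelial markers (4 of 17 higher, 4 adjusted over the list alone) had a fry adjusted p of 0.092 (0.0147 without LPab high protein replicate 4). In all 1311 of 14006 genes passed, 578 higher and 733 lower in LPgd.

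Compared with LPgd, IELgd libraries were lower in type 17 and immediate early genes. All 14 measured type 17 genes were lower, also when adjusted over the list alone (fry adjusted p = 8.91e-10; 0.000718 with an estimated correlation), and Il22 averaged 164 ± 101 and 221 ± 79.4 CPM in LPgd and 0.991 ± 1.78 and 0.175 ± 0.35 CPM in IELgd. The immediate early gene Fos (chromosome 12, 85473890 to 85477273) had a log2 fold change of -6.10 ± 0.34 and Dusp1 of -6.46 ± 0.41, and 12 of 15 genes of that list were lower (13 adjusted over the list alone, fry adjusted p = 2.12e-09). Of 17 cytotoxic and NK receptor genes 8 were higher and 2 lower (13 and 2 adjusted over the list alone, fry adjusted p = 0.000306, and adjusted p = 0.147 with an estimated correlation). Gzmb was higher by 1.84 ± 0.25, Klrd1 by 2.90 ± 0.40 and the epithelial-retention integrin Itgae by 1.44 ± 0.21. Gzma was higher by 1.42 ± 0.33 and Ahr lower (log2 fold change -1.24 ± 0.23). Il17a averaged 5.36 ± 3.56 and 7.51 ± 2.51 CPM on high carbohydrate and high protein in LPgd and 0 and 0.073 ± 0.0859 CPM in IELgd (adjusted p = 5.01e-05). Areg averaged 4.37 ± 2.91 and 3.94 ± 2.86 CPM in LPgd and 0.0742 ± 0.092 and 0.454 ± 0.66 CPM in IELgd (adjusted p = 0.0034). Jag2 did not pass (3.56 ± 1.35, adjusted p = 0.103; 0.0238 without LPgd high carbohydrate replicate 1). Markers of other cells differed too. Myeloid markers (8 of 10 lower, 9 adjusted over the list alone, fry adjusted p = 1.74e-08), stromal markers (6 of 6 lower, 6 adjusted over the list alone, 1.49e-06) and B and plasma cell markers (5 of 9 lower, 5 adjusted over the list alone, 1.3e-05) were lower in IELgd. C1qa averaged 41.3 ± 15.5 CPM in LPgd on high carbohydrate. The pancreatic enzyme gene Cpa1 averaged 1110 ± 1506 CPM there, with a range from 115 to 2842. Epithelial markers (6 of 17 higher, adjusted over the list alone 10 higher and 1 lower; fry adjusted p = 0.0102, and adjusted p = 0.247 with an estimated correlation) and the Paneth cell defensin Defa17, by 5.89 ± 0.86, were higher in IELgd. Erythroid markers were higher as a list (1 of 5, 5 adjusted over the list alone; fry adjusted p = 0.00449, and adjusted p = 0.174 with an estimated correlation). In all 1794 of 13844 genes passed, 670 higher and 1124 lower. With limma on log2(TPM + 1) the split was 1205 to 847, and the median log2 fold change of that fit differed from that of edgeR by 0.2.

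IELab differed from LPab in the same contrast of layers by 3609 of 12292 genes, 1678 higher and 1931 lower. Il22 (chromosome 10, 118204942 to 118210047) averaged 99.0 ± 32.2 and 130 ± 42.6 CPM in LPab and 0 and 0.591 ± 0.756 CPM in IELab. All 13 measured type 17 genes (fry adjusted p = 2.25e-10) and all 7 type 2 genes (9.58e-10) were lower in IELab, with the same counts adjusted over the list alone. So were 11 of 16 immediate early genes (12 adjusted over the list alone, 8.5e-09), such as Fos (log2 fold change -4.95 ± 0.33) and Junb (-4.12 ± 0.27). Ctla4 (-5.41 ± 0.36) and Ifng (-4.75 ± 0.42) were lower as well. Itgae was higher by 2.10 ± 0.20, Fcer1g by 3.25 ± 0.33, Gzma by 2.29 ± 0.37 and Gzmb by 1.11 ± 0.22. Il17a averaged 0.408 ± 0.449 and 0.0784 ± 0.157 CPM in IELab against 95.1 ± 49.5 and 53.8 ± 18.9 CPM in LPab (adjusted p = 1.04e-08), and Areg 0.127 ± 0.254 and 0.257 ± 0.344 against 18.0 ± 7.76 and 32.9 ± 19.3 CPM (adjusted p = 3.13e-07). Ahr did not pass (-0.10 ± 0.27, adjusted p = 0.805), and Jag2 was below the count filter. Stromal (6 of 6, fry adjusted p = 8.5e-09) and myeloid (6 of 8 lower and 1 higher, 9.08e-11) markers were lower in IELab, with the same counts adjusted over the list alone. B and plasma cell markers were lower as a list (5 of 8 lower and 1 higher, 5 and 1 adjusted over the list alone, fry adjusted p = 0.0005, and adjusted p = 0.287 with an estimated correlation). Epithelial markers were higher in IELab (9 of 17, 11 adjusted over the list alone, fry adjusted p = 0.0161, and adjusted p = 0.352 with an estimated correlation). That call ended with the ribosomal RNA share as a covariate (adjusted p = 0.0661). The goblet cell mucin Muc2 was higher by 4.07 ± 0.65. With limma on log2(TPM + 1) the split was 868 to 2136, and the median log2 fold change of that fit differed from that of edgeR by -0.16. With the ribosomal RNA share as a covariate 1805 genes passed.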

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

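The tests of the ribosomal RNA share as a covariate, of leaving out ribosomal RNA and G or C run models, and of other G or C run transcripts against Gm19220 were chosen only after the result was seen.

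Of 358 sets of 4 libraries of 1 group, 24 held a library far from the other 3 by Dixon's criterion. Chance gives 17.9 where values are normally distributed. In each of these sets, the distance of that library to the nearest other is given as a share of the whole range of the group. A library alone above 0 always has a share of 1, so 17.9 does not hold for genes near 0 counts. Such libraries held from 0.0947 CPM (Foxp3) to 1.01 CPM (Cd28). In epithelium, high protein replicate 2 stood apart for Gpi1 (0.855) and Tkfc (0.837), high carbohydrate replicate 2 for Fbp1 (0.834) and high protein replicate 4 for Reg3g (0.889). In IELgd on high protein, replicate 4 was the only library above 0 for Cd28, Dcn and Foxp3 (share 1 each) and stood apart for Klf2 (0.894) and Per2 (0.923), and replicate 3 was the only one above 0 for Il22 (share 1). In IELgd on high carbohydrate, replicate 3 stood apart for Foxp3 (share 1) and Ndufb3 (0.83), and replicate 4 for Il22 (0.913). In IELab, high carbohydrate replicate 1 stood apart for Areg (share 1) and Ctla4 (0.867), and high protein replicate 3 for Il10 and Il17a (share 1 each). In LPab, high protein replicate 1 stood apart for Blk (0.837), high carbohydrate replicate 1 for Cd4 (0.838) and high protein replicate 4 for Hbegf (0.897). For the share of counts on Gm19220, epithelial high protein replicate 2 (0.946), IELgd high carbohydrate replicate 2 (0.939), IELab high protein replicate 1 (0.86) and LPab high protein replicate 1 (0.924) stood apart.

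The diet effect differed between LPgd and LPab in 776 genes by the interaction test. That count moved by over 1.5 times without LPgd high carbohydrate replicate 1 (455), LPab high carbohydrate replicates 2, 3 and 4 (398, 449 and 363) and LPab high protein replicates 1, 3 and 4 (1381, 358 and 400). The log2 differences were 4.66 for AY036118, 5.49 for Fzd5, 5.37 for Taf2, 5.08 for Lrrc8a, 3.44 for Notch1, 3.80 for Notch2, 3.58 for Nr4a1, 5.93 for Zfp683, 3.40 for Prdm1, 3.04 for Slc7a5, 3.16 for Per1, -2.31 for Rsl24d1, -1.92 for Ttc5 and -1.49 for Mthfd2. Of these calls some ended when certain single libraries were left out (adjusted p without each in parentheses), which also leaves fewer samples. Slc7a5 did not pass without any 1 of LPgd high carbohydrate replicate 1 (0.0588), LPgd high protein replicates 2 and 3 (0.0512 and 0.0639), LPab high carbohydrate replicates 2, 3 and 4 (0.0598, 0.0568 and 0.0612) and LPab high protein replicate 3 (0.065). Mthfd2 did not pass without any 1 of LPgd high carbohydrate replicates 1 and 3 (0.109 and 0.0789), LPgd high protein replicates 1, 2 and 3 (0.0601, 0.0537 and 0.0718), LPab high carbohydrate replicates 1, 2 and 4 (0.0807, 0.0777 and 0.0724) and LPab high protein replicates 2, 3 and 4 (0.0538, 0.0755 and 0.0727). Slc7a5 (adjusted p = 0.0773) and Per1 (0.067) did not pass with limma on log2(TPM + 1). The list tests of the difference had adjusted p of 0.0364 for amino acid transport, 0.0364 for tissue residency, 0.0493 for Notch genes, 0.0266 for γδ receptor genes and 0.022 for αβ receptor genes, and an adjusted p = 0.675 each with an estimated correlation. Amino acid transport did not pass without any 1 of LPgd high carbohydrate replicates 1 and 2 (0.0621 and 0.0586), LPgd high protein replicate 2 (0.0516), LPab high carbohydrate replicates 2, 3 and 4 (0.0671, 0.0529 and 0.0524) and LPab high protein replicate 3 (0.0754). Tissue residency did not pass without any 1 of LPgd high carbohydrate replicates 1 and 2 (0.0586 and 0.0586), LPgd high protein replicate 2 (0.0516), LPab high carbohydrate replicates 2, 3 and 4 (0.0671, 0.0588 and 0.0524) and LPab high protein replicates 3 and 4 (0.0808 and 0.076). The Notch list did not pass without any 1 of LPgd high carbohydrate replicates 1, 2 and 3 (0.0868, 0.0586 and 0.112), LPgd high protein replicate 2 (0.078), LPab high carbohydrate replicates 2, 3 and 4 (0.0787, 0.0776 and 0.088) and LPab high protein replicates 2, 3 and 4 (0.059, 0.1 and 0.103). The γδ receptor list did not pass without any 1 of LPgd high carbohydrate replicates 1 and 2 (0.0983 and 0.0524), LPgd high protein replicate 2 (0.108), LPab high carbohydrate replicates 1, 2 and 4 (0.12, 0.0618 and 0.0521) and LPab high protein replicate 1 (0.0604). The αβ receptor list did not pass without LPgd high protein replicate 2 (0.0516).

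Between IELgd and LPgd the diet effect differed in 648 genes. This count moved as far without IELgd high carbohydrate replicates 2, 3 and 4 (371, 376 and 362), IELgd high protein replicates 1, 3 and 4 (982, 386 and 368), LPgd high carbohydrate replicate 1 (261) and LPgd high protein replicate 2 (217). The log2 differences were -4.72 for AY036118, -8.21 for Pls1, -5.66 for Taf2, -4.15 for Notch1, -3.51 for Per1, -7.23 for Per2, -7.48 for Slc7a8, -3.37 for Slc7a5, 3.33 for Klre1, 2.68 for Ndufb3 and 2.09 for Sat1. Of these calls some ended when certain single libraries were left out (adjusted p without each in parentheses), which also leaves fewer samples. Slc7a8 did not pass without LPgd high carbohydrate replicate 1 (0.0562). Slc7a5 did not pass without any 1 of IELgd high carbohydrate replicates 2 and 3 (0.0516 and 0.0519), IELgd high protein replicate 3 (0.055), LPgd high carbohydrate replicate 1 (0.0758) and LPgd high protein replicates 2 and 3 (0.0713 and 0.0571). Klre1 did not pass without any 1 of IELgd high carbohydrate replicates 3 and 4 (0.0659 and 0.06), IELgd high protein replicate 4 (0.0553), LPgd high carbohydrate replicates 1, 2 and 3 (0.0505, 0.0543 and 0.0655) and LPgd high protein replicate 2 (0.0853). Ndufb3 did not pass without any 1 of LPgd high carbohydrate replicate 1 (0.0505) and LPgd high protein replicate 2 (0.0624). Sat1 did not pass without any 1 of LPgd high carbohydrate replicates 2 and 3 (0.0549 and 0.0563) and LPgd high protein replicate 2 (0.0658). Per2 (adjusted p = 0.0539), Slc7a8 (0.09) and Slc7a5 (0.056) did not pass with limma on log2(TPM + 1). The list tests had adjusted p of 0.0263 for amino acid transport and 0.038 for clock genes, and an adjusted p = 0.606 each with an estimated correlation. Both list calls ended with DESeq2 size factors (adjusted p = 0.0527 each). The transport list did not pass without any 1 of IELgd high carbohydrate replicates 2 and 4 (0.107 and 0.0624), IELgd high protein replicate 3 (0.0662), LPgd high carbohydrate replicate 1 (0.0814) and LPgd high protein replicates 2 and 3 (0.101 and 0.0599). The clock list did not pass without any 1 of IELgd high carbohydrate replicates 1, 2, 3 and 4 (0.0972, 0.107, 0.0671 and 0.0624), IELgd high protein replicates 2 and 3 (0.0601 and 0.0662), LPgd high carbohydrate replicates 1 and 3 (0.104 and 0.106) and LPgd high protein replicates 2 and 3 (0.101 and 0.101). Transcripts outside the annotation held up to 1.35% of the counts of a library and entered no comparison.

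The genes of the LPgd and LPab interaction went with the share of counts on ribosomal RNA models. In IELab libraries, within each diet, 96.6% of 716 such genes had a slope on that share with the sign of the interaction. In 1000 random sets of genes that were not called, matched on mean expression, the median was 44.8% (range 38.1 to 50.1%). These sets do not keep the correlation between the called genes, so their range cannot say how far 96.6% lies from chance. A trend that libraries share whatever the diet may contribute. Counts on the ribosomal models were not needed for most calls, since 765 of the 776 genes were among the 809 that passed without these models and the G or C run transcripts, removed together. With the share as a covariate 0 genes passed in edgeR, the median absolute log2 difference of 771 genes went from 2.87 (median SE 0.64) to 0.45 (median SE 1.4), and the call ended both because the estimates shrank and because their error grew. The share separates the diets in LPgd and in LPab, so that trend and an effect of diet on γδ and αβ cells, which the design names, cannot be told apart here. It also separates them in IELgd, so the same holds for the interaction of IELgd with LPgd. T cell markers separated the diets in LPgd (1.38 to 2.48% on high carbohydrate and 2.82 to 7.38% on high protein). In LPab they overlapped (1.63 to 2.15% and 1.78 to 2.44%). The list of T cell markers includes Gzma, Gzmb and Ccl5, so its share depends on their expression as well as on the number of T cells. A difference in the cells sorted cannot be told apart either, and was not tested.

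Gm19220, a pseudogene with a run of 33 G or C bases, held 25.3, 11.3, 5.29 and 1.69% of the counts of the high carbohydrate epithelial libraries and 1.35 to 22% of the high protein ones. All 54 genes called for diet were among the 63 that passed without G or C run and ribosomal RNA models, removed together, so these calls did not need its counts. Without the 3 libraries highest in Gm19220 (high carbohydrate replicates 1 and 2 and high protein replicate 2) 218 genes passed, 50 of the 54 among them, so whether these libraries differ in other ways stays open. Its share rose with the share on the other G or C run transcripts over 8 libraries (Spearman rho 0.952, permutation p = 0.00114; Pearson r 0.902, permutation p = 0.00109, adjusted p = 0.00218 over 2 relations, and r 0.725 without the 2 libraries farthest from the median), so reads of homopolymer G or C are a candidate source. With A or T run transcripts rho was 0.071 (permutation p = 0.882) and r 0.241 (permutation p = 0.609; -0.363 without the 2 farthest), which leaves runs of any base open. These relations were computed in the epithelial libraries alone. Gm19220 also held 15.90 and 12.49% of counts in IELab high carbohydrate replicates 2 and 4. All G or C run transcripts, Gm19220 among them, held 15.95 and 12.52% there, against 30.06% in epithelial high carbohydrate replicate 2. The candidate source is therefore named for epithelium only, and the source in T cell libraries was not tested. No biological explanation was tested.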

How the results depend on the processing

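The covariate, the fits without ribosomal RNA and G or C run models and those without 2 or 3 epithelial libraries were chosen only after the result was seen. For counts that moved by over 1.5 times the cause was not tested, except that leaving out libraries leaves fewer samples.

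With the DESeq2 Wald test the counts were 149 in epithelium, 224 in IELgd, 961 in LPgd, 2 in IELab and 240 in LPab for diet, 2, 1762 and 1562 for the interactions of IELgd with IELab, LPgd with LPab and IELgd with LPgd, and 2259 for IELgd against IELab. With voom they were 188 in epithelium, 39 in LPgd, 17 in LPab and 2351 for IELgd against IELab. With limma on log2(TPM + 1) they were 0 in epithelium, 2 in IELgd, 52 in LPgd, 1 in IELab and 2 in LPab. The median log2 fold change of this fit differed from that of edgeR by 0.2 in IELgd and 0.18 in LPab. It differed by 0.35 and 0.14 in the interactions of IELgd with IELab and with LPgd. This fit and that of edgeR keep different genes and use different scales, so these are not shifts of the same genes. Without a filter on low counts the gene counts were 290, 407, 861, 122 and 165 for diet in epithelium, IELgd, LPgd, IELab and LPab. They were 97, 1165 and 1274 for the interactions in the order above and 2327 for IELgd against IELab. A CPM of at least 5 gave 33 in LPgd, the length offset 34 in epithelium and 65 in LPgd, and all T cell libraries in 1 fit 271 in LPgd. Of 78 lists that passed fry, the median over members turned in 1, the type 1 genes between LPgd and LPab, from -0.02 with TMM to 0.05 with DESeq2 size factors.

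With the ribosomal RNA share as a covariate, counts were 0 in LPgd, 0 and 3 for the interactions of LPgd with LPab and with IELgd, 503 for IELgd against IELab and 1805 for IELab against LPab. Of the LPgd and LPab interaction lists, amino acid transport (adjusted p = 0.996), tissue residency (0.743), Notch (0.743) and αβ receptor genes (0.915) then had the opposite direction. Without ribosomal RNA and G or C run models 4 genes passed in LPgd, and without the 3 epithelial libraries highest in Gm19220 218 passed in epithelium. Without epithelial high carbohydrate replicate 1 and high protein replicate 2, adjusted p of the 4 epithelial lists were 0.103 for carbohydrate-response, 0.103 for peptide digestion, 0.0915 for amino acid transport and 0.107 for interferon genes.

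In no comparison were all pairs of same-numbered libraries correlated above 0.1, or all libraries closest to their own number, so the libraries were not treated as paired. This criterion was applied when the counts with the block were already known. Some pairs did correlate, such as 3 of 8 over 0.1 between IELgd and IELab (highest 0.266). Between IELab and LPab, high carbohydrate replicates 2, 3 and 4 each matched their own number best (0.138, 0.198 and 0.095). Pairing of these libraries is therefore not excluded. Correlations ran from -0.135 to 0.043 in epithelium and from -0.225 to 0.273 elsewhere. The replicate block gave 30 genes in epithelium, 1 in LPab, 67 and 100 for the interactions of LPgd with LPab and with IELgd, 687 for IELgd against IELab and 797 for LPgd against LPab. In epithelium the 4 lists that passed had an adjusted p from 0.088 to 0.147 with the block.

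Leaving out 1 library gave 17 to 103 genes in epithelium, 0 to 44 in IELgd (44 without high protein replicate 1, 1 without replicate 4), 4 to 10 in LPgd, 0 to 0 in IELab and 0 to 139 in LPab (139 without high protein replicate 1). It gave 0 to 0, 358 to 1381 and 217 to 982 for the interactions in the order above, and 840 to 2325, 968 to 1395, 1428 to 2044 and 2923 to 4243 for IELgd against IELab, LPgd against LPab, IELgd against LPgd and IELab against LPab. Epithelial high carbohydrate replicate 1, with 284149 counts, is the shallowest library.

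Of 35 splits of the 8 epithelial libraries only 1, the real one, gave as many as 54 genes (highest other 9). That is the smallest share 35 splits allow and was not adjusted over the comparisons, so it argues against chance without excluding it. For diet in IELgd, IELab and LPab (35 of 35 splits, highest others 1, 1 and 7) and for the interaction of IELgd with IELab (100 of 100, highest other 430) the real count is 0, which every split reaches, so the splits say nothing of chance there. LPgd has 10 splits, too few for a share under 0.05 (real 18, highest other 1). Of 100 splits 1 reached the real count for the interactions of LPgd with LPab (776, highest other 7) and with IELgd (648, highest other 373), and for the populations (1448, 1311, 1794 and 3609, highest others 107, 41, 441 and 1664). The splits with 373, 441 and 1664 genes each moved only 2 libraries from the real groups. The split with 430 genes moved 6 of 16 and points to a structure of the samples, which was not tested.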

Other observations

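Some further gene groups differed between IELgd and LPgd, and their values are given for γδ cells. They are not all particular to γδ cells. The lists of ligands that act on epithelium and of glycolysis genes also passed fry between IELab and LPab. Their median log2 fold changes there were -2.47 and -0.46, while the clock list did not pass. Of 18 genes for ligands that act on epithelium 11 were lower in IELgd than in LPgd (adjusted over the list alone 13 lower and 2 higher, fry adjusted p = 1.21e-06, and 0.0121 with an estimated correlation). Myeloid, stromal and B and plasma cell markers were lower in IELgd too, and which cells gave these transcripts was not tested. Of 14 clock genes 8 were lower in IELgd, also 8 adjusted over the list alone (fry adjusted p = 4.1e-05, and 0.0326 with an estimated correlation), and Nr1d1, a clock repressor, averaged 2.90 ± 0.841 and 6.61 ± 5.79 CPM on high carbohydrate and high protein in IELgd (n = 4 each) against 315 ± 49.8 and 97.3 ± 71.7 CPM in LPgd (n = 3 each). Of 17 glycolysis genes 4 were lower in IELgd, 5 adjusted over the list alone (fry adjusted p = 5.82e-06, and 0.0261 with an estimated correlation), among them the hexokinase Hk2, with a log2 fold change of -3.90 ± 0.33.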
